A study of Mus musculus with 12 samples.

How the data were processed

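RNA was sequenced from thymic epithelial cells (TECs), the stromal cells that present antigens to developing T cells, sorted from fetal thymic organ cultures of C57BL/6 mice. Per the labels' protocols, lobes were taken on embryonic day 15.5 and kept for 4 to 5 days with 1.35 mM 2'-deoxyguanosine, which kills thymocytes. They then spent 3 days with 10 µg/mL of an antibody that activates RANK, a receptor whose signal brings on AIRE, the regulator that lets medullary TECs transcribe genes of other tissues. The labels give 4 groups of 3 biological replicates: tamoxifen-treated cultures of a control genotype, tamoxifen-treated cultures in which a Cre recombinase removes floxed Kat7, wild-type cultures with the solvent DMSO, and wild-type cultures with WM-3835, an inhibitor of KAT7 (also called HBO1). The titles of the inhibitor samples spell the compound WM-3825, while their treatment field and the series design give WM-3835, the name used here. The labels do not detail the control genotype, and they give no dose or duration for the inhibitor.

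The deposited values are raw counts: per the file headers, each file pairs an Entrez gene ID with a symbol, a gene length and a count. The authors counted with featureCounts against mm10, per the submitters' processing notes. The aligner, the gene annotation and the strand setting are not given in the sources used here, nor is whether 1 count stands for a read or a read pair. The library kit named in the labels (TruSeq RNA v2, read as 75-base pairs) does not mark strand, so reads of a gene and of a gene antisense to it cannot be told apart. Counts of near-identical copies are uncertain, because how shared reads were counted is not stated. This bears on Xist and its antisense partner, Ccl21a, Acot1 and Acot2, H2-DMb2, Gsdmc2, Ang4, and the Sprr, kallikrein, histone, ribosomal protein and mitochondrial protein families.

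Each file lists 27179 genes. The 1312 without a symbol were left out, and they held 0.657% to 0.743% of a library's counts. Among the 25867 with a symbol, 25234 (97.6%) were matched by Entrez ID to a RefSeq gene position on GRCm38.p6, the assembly also called mm10, and coordinates are given on it. Total counts per library ran from 26656847 to 52368012. Depth sets a floor on rare transcripts, and replicate spread was larger than counting error: between replicates, squared deviations were 8.57 to 51.2 times those of counting alone.

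Differences between groups were tested with edgeR 4.0.16 in R 4.3.3. Libraries were scaled by TMM, genes with too few counts were removed by filterByExpr, which left 18670, and a quasi-likelihood model with 4 group means was fitted to all 12 libraries. Changes are log2 fold changes with their standard errors (SE). A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, over all genes of the comparison. The comparisons were knockout against control, WM-3835 against DMSO, the difference between those effects, and DMSO against control. The last is descriptive, since treatment and genotype label differ between its groups. CPM values are TMM-scaled and given as mean and SD.

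Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01, and Benjamini-Hochberg adjustment over 49 of the 50 lists, those with at least 3 tested genes. Camera with a correlation estimated from the data and fry, which asks whether a list's genes move one way on balance, were run beside it. Members are counted at the adjusted p over all genes and again adjusted over the list alone. Another 3 lists were written after the gene results were seen, without the genes already looked at, and adjusted among themselves. Where every library of a group had 0 counts of a gene, the list's median was also computed with that gene at the bound set by 3 counts over the group.

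The lists, the tests, the other settings to be tried and the rule for named genes were fixed before the data were examined. The rule takes, per main comparison, Kat7 and Aire, the 10 largest rises and 10 largest falls among called genes with mean log2 CPM of at least 1 whose 3 libraries of one group all lay above the 3 of the other, and up to 4 members with the smallest adjusted p of each list described. Predicted genes and clone names were left out, and a few genes that the rule takes are not listed in the text. Chance alone separates 3 libraries from 3 others in 10% of genes. Genes named for the 3 later lists were chosen after their values were seen, as were those of the lists described for DMSO against control.

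For the number of genes detected, every library was thinned 5 times to the smallest total over genes with a symbol, 26473241 counts, and group means were compared by a two-sided exact permutation test. With 3 libraries against 3 its smallest possible p is 0.1.

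Other settings fixed at that stage were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of CPM over 1 in 3 libraries, the replicate number as a block, each comparison fitted on its own 6 libraries, and each replicate left out. Added after seeing the data were limma-voom with a quality weight per group, robust edgeR, Xist as a covariate, the knockout library without Xist as the only knockout library, and a fit without genes on X and Y. The lone library in that fit is assumed to vary like the others.

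The tests were checked on counts simulated from the real means and library sizes for 18589 genes, each with the same spread in all groups. The real spread differed between groups, so the rates below do not cover that difference. For the knockout comparison, edgeR called 59.8% of genes changed 2-fold and 76.8% of those changed 4-fold, and 4.3% of its calls were false. For WM-3835 against DMSO it called 66.3% and 78.4%, with 4.1% false. For the difference between the effects it called 57.4% and 74.5%, with 4.8% false. DESeq2 made 14.6% false calls in the simulated knockout comparison and 17.6% in that of WM-3835. In the simulated knockout comparison, camera and fry each found the list that was changed. Simulated genes varied independently, while the estimated correlation within real lists reached 0.638 (mitosis). This check therefore does not cover correlation between genes.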

Results

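Gene expression was measured by RNA sequencing in TECs from 12 organ cultures, 3 each of control, Kat7 knockout, DMSO and WM-3835 cultures. The control libraries held 42985014, 40362828 and 35358509 counts and the knockout libraries 36829303, 27353357 and 29098783. The DMSO libraries held 52368012, 26656847 and 42873803 counts and the WM-3835 libraries 45502878, 38667904 and 29113496. Replicates differed most among the controls: the biological coefficient of variation was 0.469 in control, 0.294 in knockout, 0.103 in DMSO and 0.125 in WM-3835 libraries. Control 1 also held more counts of the ribosomal RNA gene Rn45s, 0.669% against 0.167% to 0.267% in the other libraries. Xist, the RNA that coats the inactive X chromosome of female cells (Entrez ID 213742, chromosome X, 103460373 to 103483233 on mm10), divided the libraries. It stood at 2.34 to 3.17 CPM in the controls, at 1709, 1191 and 4.94 CPM in the knockout libraries, and at 846 to 2118 CPM in the DMSO and WM-3835 libraries. Ddx3y, a gene of the Y chromosome, was present in every library, at 25.2 to 112 CPM.

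The knockout comparison asks which genes of TECs depend on KAT7, a histone acetyltransferase. Kat7 itself (Entrez ID 217127, chromosome 11, 95271853 to 95310246 on mm10) fell from 80.5 ± 7.38 CPM in control to 0.762 ± 0.138 CPM in the knockout (mean ± SD, n = 3 each), a log2 change of -6.74 (SE 0.13, adjusted p = 1.31e-16). In the wild-type cultures it stood at 87.3 ± 2.37 CPM with DMSO and 99.4 ± 0.953 CPM with WM-3835, a log2 difference of 0.19 (SE 0.09) that did not pass (adjusted p = 0.159). Fitted on those 6 libraries alone, the difference passed at 0.18 (adjusted p = 0.026), and with quality weights per group likewise (0.18, adjusted p = 0.0114).

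Aire, the gene of the AIRE regulator (Entrez ID 11634, chromosome 10, 78030022 to 78043610 on mm10), was lower in both treated groups, and more so with the inhibitor. It stood at 634 ± 36.2 CPM in control and 536 ± 43.9 CPM in the knockout, a log2 change of -0.24 (SE 0.08, adjusted p = 0.0457). With WM-3835 it fell from 1199 ± 69.9 to 556 ± 40.5 CPM, a log2 change of -1.11 (SE 0.08, adjusted p = 3.35e-08), and the changes differed by 0.87 (adjusted p = 4.7e-05). The fall of Aire in the knockout did not pass in several other fits. The log2 change was -0.19 without control 2 (adjusted p = 0.152), -0.23 without control 3 (0.0861), -0.24 without knockout 1 (0.111) and -0.17 without knockout 2 (0.222). It was -0.24 without the filter on low counts (adjusted p = 0.0508), -0.25 on the 6 libraries alone (0.0904), -0.24 with quality weights (0.152), -0.17 with Xist as a covariate (0.333) and -0.12 with knockout 3, the library without Xist, as the only knockout library (0.57).

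**Figure D1:**
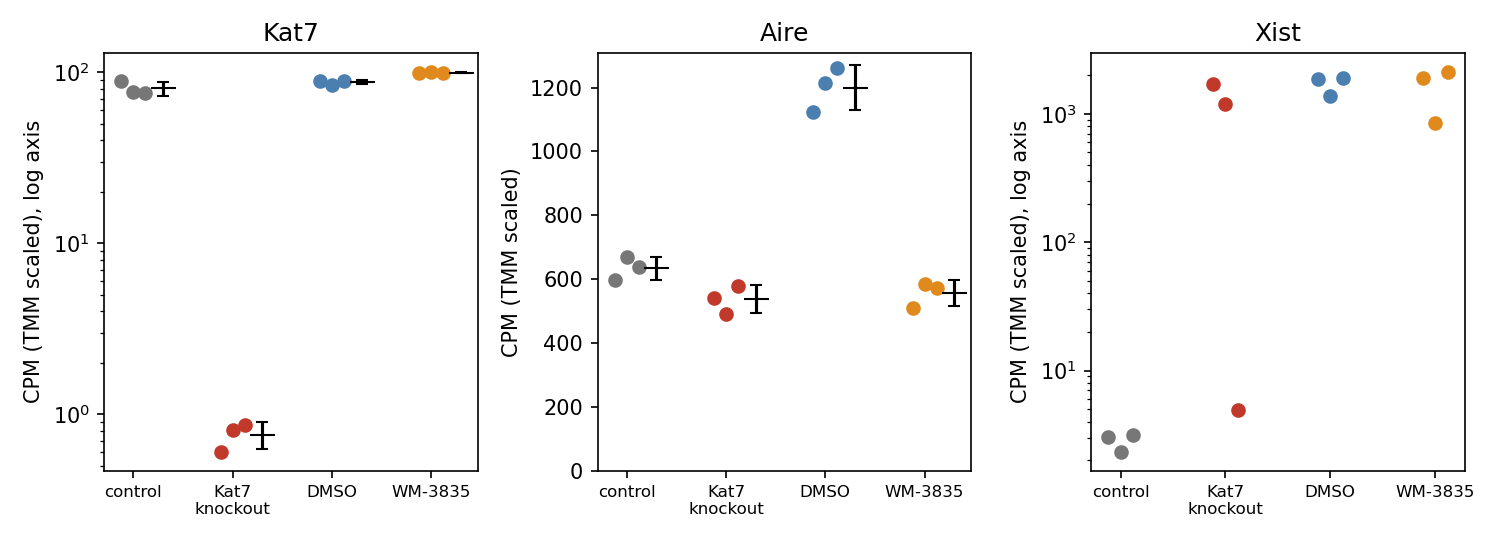
Level of Kat7, Aire and Xist in each library, in TMM-scaled CPM by group, with log axes for Kat7 and Xist; points are libraries, and crosses and bars in the panels of Kat7 and Aire are mean ± SD (n = 3). Kat7 is near 1 CPM in the knockout libraries, Aire is highest with DMSO, and Xist is low in the 3 controls and in knockout 3.

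The largest falls in the knockout included genes known from stomach and gut. Pgc, the precursor of a stomach protease, fell by 3.43 on the log2 scale (SE 0.55, adjusted p = 0.000437), from 13.9 ± 2.84 to 1.32 ± 1.30 CPM. Muc2, the main mucin of the intestine, fell by 2.92 (SE 0.57, adjusted p = 0.00221), and Ang4, an antimicrobial protein of the gut, fell by 2.81 (SE 0.32, adjusted p = 1.64e-05). The other large falls were Bpifb5 (-3.25), Gsdmc2 of the gasdermins (-3.16), the collagenase gene Mmp13 (-3.07), Thy1 (-3.02), the growth factor gene Hbegf (-2.92) and Cpe, whose product trims prohormones (-2.91), at adjusted p of 0.00272 or less. Hbegf varied widely among the controls, at 59.6 ± 29.7 CPM against 7.82 ± 1.27 CPM in the knockout. The fall of Thy1 did not pass with Xist as a covariate (-2.55, adjusted p = 0.134) or with knockout 3 alone (-3.60, adjusted p = 0.0509).

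The largest rises were smaller than the falls, Xist apart. Gpr85, an orphan receptor of the brain, rose by 2.45 (SE 0.34, adjusted p = 0.000114), from 1.11 ± 0.414 to 6.03 ± 2.42 CPM. Calb1, a calcium-binding protein, rose by 2.25 (SE 0.35, adjusted p = 0.000317), Lonrf2 by 1.91 (SE 0.26, adjusted p = 0.0001) and Scn1a, a neuronal sodium channel, by 1.86 (SE 0.28, adjusted p = 0.000274). Xist rose by 8.41 (SE 1.20, adjusted p = 0.000152), carried by knockout libraries 1 and 2, and did not pass with limma-voom (6.32, adjusted p = 0.414), with quality weights (6.31) or with knockout 3 alone (0.80). Pnma2 (1.89), the sperm channel gene Catsperg1 (1.83), Rgs20 (1.82), Trim67 (1.82) and Tmem200c (1.78) also rose, at adjusted p of 0.0201 or less. Pnma2 did not pass without control 2 (adjusted p = 0.0562) or knockout 2 (0.0604), Trim67 without control 1 (0.0599) or knockout 3 (0.0797), and Tmem200c without knockout 1 (0.0511). These genes, and Catsperg1 and Rgs20, did not pass on the 6 libraries alone or with quality weights per group, which also ended the call of Calb1; the log2 changes in these fits were 1.76 to 2.31. Pnma2 (1.84) and Tmem200c (1.31) did not pass with Xist as a covariate either, nor did Pnma2 (1.87), Tmem200c (0.96), Rgs20 (2.22) and Trim67 (2.25) with knockout 3 alone.

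Genes of the medullary epithelium were lower in the knockout. Of 14 measured markers of immature medullary cells, 7 fell and the other 7 did not pass, and 9 fell adjusted over the list alone (median log2 change -0.44, camera adjusted p = 8.84e-07; adjusted p = 0.106 with an estimated correlation). Among them were the chemokine gene Ccl21a (-1.33, SE 0.14), Tnfrsf11b, which encodes a decoy for the RANK ligand (-1.01, SE 0.11), and Trp63, a regulator of epithelial stem cells (-0.62, SE 0.08). Of 18 markers of mature medullary cells, 10 fell, and 12 fell adjusted over the list alone (median -0.25, camera adjusted p = 0.000387; adjusted p = 0.617 with an estimated correlation). H2-DMb2, which helps load peptides on MHC class II, fell by 0.87 (SE 0.10). The count of 10 was less stable than that of 7: it was 3 without control 2, 3 without knockout 1, 2 without knockout 2 and 3 without knockout 3. It was 6 on the 6 libraries alone, 2 with quality weights, 1 with Xist as a covariate and 2 with knockout 3 alone.

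Antigens that AIRE is known to bring on in the thymus were lower as a group. Of 20 such genes measured, 6 fell and the other 14 did not pass, with 6 also adjusted over the list alone (median -1.43, camera adjusted p = 0.000387; adjusted p = 0.106 with an estimated correlation). Csn2, a milk casein (Entrez ID 12991, chromosome 5, 87692619 to 87699429 on mm10), fell from 199 ± 23.9 to 82.2 ± 8.07 CPM, a log2 change of -1.28 (SE 0.11, adjusted p = 1.26e-06). S100a8, a protein of neutrophils, fell by 1.62 (SE 0.33) and Muc6, a stomach mucin, fell by 1.66 (SE 0.38). Of 16 antigens that depend on Fezf2, 1 rose and 1 fell (median -0.34, camera adjusted p = 0.37). Of 8 antigens independent of AIRE, none was called (median 0.26, camera adjusted p = 0.602). Camera sets a list against all other genes, not against genes of like expression. The lowest expression quartile was lower as well (median -0.464), so a fall particular to AIRE targets is not shown. The count of 6 became 3 on the 6 libraries alone, 2 with Xist as a covariate and 1 with knockout 3 alone.

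Some lists for other specialised TECs passed downward in the knockout, and that of cortical markers passed upward. Of 16 genes of enterocyte- and hepatocyte-like cells, 5 fell, and 6 adjusted over the list alone (median -0.39, camera adjusted p = 0.013; adjusted p = 0.415 with an estimated correlation), with the gut defence genes Reg3g (-1.37, SE 0.18) and Reg3b (-2.29, SE 0.53) among them. Of 15 tuft-cell genes, 2 fell, and 3 adjusted over the list alone (median -0.42, camera adjusted p = 0.0353; adjusted p = 0.728 with an estimated correlation), Il17rb by -0.70 (SE 0.16). Of 16 genes of the cornified envelope of skin, 4 fell, and 4 adjusted over the list alone (median -0.99, camera adjusted p = 0.00428; adjusted p = 0.106 with an estimated correlation), Sprr1a by -0.96 (SE 0.14). Of 16 cortical markers, 5 rose and 2 fell, the same counts as adjusted over the list alone (median 0.23, camera adjusted p = 0.0101; adjusted p = 0.728 with an estimated correlation). The peptidase gene Enpep rose by 0.91 (SE 0.09) and the endocytic receptor gene Ly75 by 0.75 (SE 0.10). The tuft, enterocyte- and hepatocyte-like and cornified envelope lists were also lower in DMSO than in control (medians -3.36, -0.75 and -0.71). Their falls in the knockout cannot be told from a high level in the controls. Lists for keratinocyte-like (2 rose and 2 fell, camera adjusted p = 0.597), neuroendocrine (0.641), muscle-like (0.169), ciliated (0.0905) and microfold-like cells (0.082) did not pass, though fry passed the last 4 downward (adjusted p from 0.011 to 0.0481).

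Single libraries carried part of these counts. The 5 enterocyte and hepatocyte genes were 3 without control 1, knockout 2 or knockout 3, 3 on the 6 libraries alone, and 2 with quality weights, Xist as a covariate or knockout 3 alone. The tuft list did not pass without control 1 (camera adjusted p = 0.397), knockout 1 (0.0633), knockout 2 (0.0619) or knockout 3 (0.052), and its 2 falls did not pass with Xist as a covariate or with knockout 3 alone. The cortical list did not pass without control 1 (camera adjusted p = 0.325). Its 5 rises were 2 without control 1, knockout 1 or knockout 2, 3 with quality weights, and 2 with knockout 3 alone. Neither the tuft list (adjusted p = 0.2) nor the cortical list (0.17) passed by fry.

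Part of the stress, cholesterol and mitosis genes moved as well. Of 15 immediate early and heat shock genes, 9 fell and 2 rose, or 11 and 3 adjusted over the list alone (median -0.37, camera adjusted p = 0.00166; adjusted p = 0.617 with an estimated correlation). Dusp1, a phosphatase that ends MAP kinase signals, fell by 0.91 (SE 0.11), and the transcription factor gene Fosb fell by 1.11 (SE 0.16). The immediate early list was also lower in DMSO than in control (median -0.61), so its fall cannot be told from a high level in the controls. Of 20 cholesterol synthesis genes, 9 fell and 1 rose, or 11 and 1 adjusted over the list alone (median -0.25, camera adjusted p = 0.000327; adjusted p = 0.415 with an estimated correlation), with Hmgcs1 at -0.41 (SE 0.10). Of 20 mitosis genes, 5 fell, and 7 adjusted over the list alone (median -0.43, camera adjusted p = 0.00134; adjusted p = 0.712 with an estimated correlation), with the spindle checkpoint gene Bub1b at -0.57 (SE 0.15). Of 16 genes of the unfolded protein and integrated stress response, 4 rose and 1 fell, or 5 and 1 adjusted over the list alone (median 0.23, camera adjusted p = 0.00536; adjusted p = 0.712 with an estimated correlation). Sesn2, induced by amino acid shortage, rose by 0.62 (SE 0.09), and Xbp1, a regulator of secretion, fell by 0.38 (SE 0.09). The list of 29 DNA replication genes did not pass (1 rose, and none adjusted over the list alone; median 0.04, camera adjusted p = 0.602).

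These counts varied between fits. With Xist as a covariate the medians were -0.28 for immediate early genes, -0.19 for cholesterol synthesis, -0.37 for mitosis and 0.13 for the stress response. The 9 immediate early falls were 4 with Xist as a covariate and 2 with knockout 3 alone. The 9 cholesterol falls were 5 without control 3, knockout 1 or knockout 2, 3 on the 6 libraries alone or with Xist as a covariate, 4 with quality weights and 1 with knockout 3 alone. The 5 mitosis falls were 10 without control 1 and 1 without control 3 or knockout 1, and they did not pass on the 6 libraries alone, with quality weights, with Xist as a covariate or with knockout 3 alone. The mitosis list did not pass without control 3 (camera adjusted p = 0.22), and the call of Bub1b was lost without control 3 (log2 -0.40, adjusted p = 0.0598) or knockout 3 (log2 -0.50, adjusted p = 0.0639). The stress response list did not pass without control 3 (camera adjusted p = 0.176), and its 4 rises were 7 without control 1 and 2 without knockout 1, on the 6 libraries alone, with quality weights, with Xist as a covariate or with knockout 3 alone. By fry, the lists of mitosis (adjusted p = 0.138), immediate early (0.0768) and stress response genes (0.17) did not pass.

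Part of the matrix and fibroblast genes were lower in the knockout. Of 18 genes of the extracellular matrix and the TGF-beta response, 5 fell and 1 rose, or 6 and 1 adjusted over the list alone (median -0.31, camera adjusted p = 0.0167; adjusted p = 0.415 with an estimated correlation). Tgfbi fell by 1.55 (SE 0.20), and Vim, a filament of mesenchymal cells, rose by 0.55 (SE 0.12). Of 15 fibroblast markers, 3 fell, Thy1 among them, and 5 adjusted over the list alone (median -0.48, camera adjusted p = 0.0132; adjusted p = 0.425 with an estimated correlation), with the proteoglycans Dcn (-1.79, SE 0.20) and Lum (-2.36, SE 0.56). Without control 1, neither the matrix list (camera adjusted p = 0.154) nor the fibroblast list (0.134) passed. The 5 matrix falls were 3 without knockout 1 or knockout 2 and with quality weights, and 2 with Xist as a covariate or knockout 3 alone. The 3 fibroblast falls were 5 without control 2 or control 3 and 1 with knockout 3 alone. Lists for thymocytes, endothelium, macrophages and dendritic cells, B cells, red cells, parathyroid, and innate lymphoid and natural killer cells did not pass in the knockout (camera adjusted p from 0.26 to 0.863).

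In all, 2646 of 18670 genes were called by edgeR in the knockout comparison, 1142 higher and 1504 lower (56.8% lower). Over the other fits the share that was lower ran from 48.8% without control 1 to 67.4% on the 6 libraries alone. More than 2-fold changes were 111 rises and 643 falls. On its own 6 libraries the comparison called 1157 genes, 1148 of them shared with the 2646. With quality weights per group it called 1180 (1167 shared), with Xist as a covariate 1057 (1021 shared), and with knockout 3 as the only knockout library 704 (625 shared). Of the list members named for the knockout, Muc6 (-1.39), Il17rb (-0.69), Hmgcs1 (-0.28), Bub1b (-0.62) and Vim (0.51) did not pass with Xist as a covariate, nor Bub1b (-0.53), Xbp1 (-0.38) and Vim (0.57) with quality weights and Bub1b (-0.58) on the 6 libraries alone. With knockout 3 alone, Muc6 (-1.06), Il17rb (-0.83), Hmgcs1 (-0.26), Bub1b (-0.68), Xbp1 (-0.40), Vim (0.43), S100a8 (-1.53), Fosb (-0.85) and Lum (-2.66) did not pass. The signs of these changes are those of the 12-library fit. With Xist as a covariate the median was -0.46 for immature and -0.16 for mature medullary markers, -1.25 for antigens that depend on AIRE, -0.65 for tuft, -0.26 for enterocyte and hepatocyte, -0.35 for matrix and -0.49 for fibroblast genes, and 0.32 for cortical markers.

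The inhibitor comparison asks what blocking KAT7 with WM-3835 does to TECs of wild-type cultures, in which all 6 libraries held Xist. Angptl4, Pdk4 and Acot1, genes of lipid use, were among the largest rises. Angptl4, an inhibitor of lipoprotein lipase (Entrez ID 57875, chromosome 17, 33774900 to 33781575 on mm10), rose from 0.288 ± 0.280 to 12.5 ± 0.541 CPM, a log2 change of 5.28 (SE 0.63, adjusted p = 8.6e-06). Pdk4, the kinase that shifts cells from glucose to fat, rose by 4.17 (SE 0.26, adjusted p = 7.77e-09), and Acot1, an acyl-CoA thioesterase, by 2.78 (SE 0.10, adjusted p = 2.12e-12). Pdgfra, a growth factor receptor, rose by 4.11 (SE 0.44, adjusted p = 2.66e-06), and the interferon-inducible Ifi207 by 3.18 (SE 0.24, adjusted p = 6.43e-08). Plekhd1 (2.74), Calb1 (2.57), Elapor1 (2.49) and Tac1, the precursor of substance P (2.39), also rose, at adjusted p of 0.00146 or less.

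Slc6a15, an amino acid transporter of neurons, fell by 4.42 with WM-3835 (SE 0.40, adjusted p = 4.04e-07), from 12.6 ± 0.471 to 0.580 ± 0.270 CPM. Thy1 fell by 3.79 (SE 0.66, adjusted p = 0.000468), Tmprss11d, a protease of the airway, fell by 3.72 (SE 0.49, adjusted p = 2.98e-05), and Ang4 fell by 3.48 (SE 0.35, adjusted p = 1.42e-06). Also lower were Tmem132e (-3.47), the sialidase gene Neu2 (-3.39), the glutamate transporter gene Slc1a2 (-3.35), Siglec15 (-3.32), Crocc2 (-3.29) and Bpifb5 (-3.23), at adjusted p of 0.00104 or less. Neu2 did not pass with limma-voom (-3.50, adjusted p = 0.107). Thy1, Ang4 and Bpifb5 were thus among the 10 largest falls of both comparisons under the rule for named genes, and Calb1 among the 10 largest rises of both.

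Cortical markers fell with the inhibitor, in contrast to the knockout. Of 16 cortical markers 13 fell and 1 rose, the same counts as adjusted over the list alone (median -0.79, camera adjusted p = 1.83e-08; adjusted p = 0.341 with an estimated correlation), and the difference between the effects passed (median difference 0.95, camera adjusted p = 2.19e-12; adjusted p = 0.345 with an estimated correlation). The T-cell growth factor gene Il7 fell by 1.16 (SE 0.13), the protease gene Ctsl fell by 0.90 (SE 0.11) and Cd83, which stabilises MHC class II, fell by 1.55 (SE 0.23), while Enpep rose by 0.73 (SE 0.09) as it had in the knockout. Of 18 mature medullary markers, 10 fell, and 10 adjusted over the list alone (median -0.33, camera adjusted p = 1.15e-06; adjusted p = 0.362 with an estimated correlation). They included H2-DMb2 (-1.04, SE 0.10), the costimulatory receptor gene Cd40 (-0.64, SE 0.09) and H2-Ab1 of MHC class II (-0.60, SE 0.08). The 14 immature medullary markers did not pass as a list (3 rose and 6 fell, the same adjusted over the list alone; median -0.17, camera adjusted p = 0.316; adjusted p = 0.624 with an estimated correlation), and the 6 falls were 3 without DMSO 2.

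Antigens that depend on AIRE were lower with the inhibitor too. Of 20 measured, 8 fell and the other 12 did not pass, with 9 adjusted over the list alone (median -2.04, and -2.04 with 1 gene at its bound, camera adjusted p = 1.18e-05; adjusted p = 0.0779 with an estimated correlation). Csn2 fell from 190 ± 10.9 to 39.4 ± 6.43 CPM, a log2 change of -2.27 (SE 0.12, adjusted p = 7.19e-10), and this exceeded its change in the knockout by 1.00 on the log2 scale (adjusted p = 0.000368). S100a8 fell by 2.14 (SE 0.34). As a list, these genes did not pass the test of the difference between the effects (median difference 0.43, camera adjusted p = 0.444). The 8 falls were 4 without DMSO 2, DMSO 3, WM-3835 1 or WM-3835 3, and 13 with quality weights. Of 16 antigens that depend on Fezf2, 5 fell and 1 rose (median -0.23, camera adjusted p = 0.157, fry adjusted p = 0.00796, downward). Of 8 antigens independent of AIRE, 1 fell (median 0.21, camera adjusted p = 0.877). The lowest expression quartile was lower as well (median -0.438), so a fall particular to AIRE targets is not shown.

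Genes of ciliated cells fell almost throughout with the inhibitor. Of 13 measured, 12 fell, and 12 adjusted over the list alone (median -1.37, camera adjusted p = 7.78e-08; adjusted p = 0.0779 with an estimated correlation). Foxj1, a regulator of motile cilia, fell by 1.37 (SE 0.17), Mcidas, which acts in the same program, fell by 2.69 (SE 0.49), and the axoneme gene Spag6l fell by 3.31 (SE 0.55). Of 12 neuroendocrine genes 4 fell, and 4 adjusted over the list alone (median -0.58, camera adjusted p = 0.0119; adjusted p = 0.266 with an estimated correlation), with the calcium channel subunit Cacna2d1 at -1.58 (SE 0.23). Of 25 kallikreins, secreted proteases, 5 fell, and 5 adjusted over the list alone (median -1.49, camera adjusted p = 0.000619; adjusted p = 0.267 with an estimated correlation), with Klk7 at -2.37 (SE 0.56). The 5 kallikrein falls were 2 without DMSO 2 or DMSO 3, 1 without WM-3835 1, 3 without WM-3835 2 or WM-3835 3, 10 on the 6 libraries alone and 11 with quality weights.

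Most interferon genes and a smaller part of the cell cycle genes rose with the inhibitor. Of 22 genes of the type I interferon response, 14 rose and 1 fell, or 15 and 1 adjusted over the list alone (median 0.41, camera adjusted p = 1.44e-08; adjusted p = 0.341 with an estimated correlation). They included the regulator Irf7 (0.82, SE 0.08), the antiviral gene Oasl1 (1.12, SE 0.11) and the RNA sensor gene Ifih1 (0.61, SE 0.08). The interferon list was lower in DMSO than in control for 14 of 22 genes (median -0.35, camera adjusted p = 3.06e-06, or 0.406 with an estimated correlation). Its rise cannot be told from a low level in the DMSO libraries. Of 29 DNA replication genes, 11 rose, and 13 adjusted over the list alone (median 0.47, camera adjusted p = 1.15e-06; adjusted p = 0.152 with an estimated correlation), with the helicase subunits Mcm5 (0.71, SE 0.12) and Mcm6 (0.63, SE 0.11). Of 20 mitosis genes, 6 rose, and 8 adjusted over the list alone (median 0.48, camera adjusted p = 9.69e-05; adjusted p = 0.511 with an estimated correlation), with Hmmr (0.70, SE 0.17) and the spindle gene Tpx2 (0.45, SE 0.11). The 11 replication rises were 7 without DMSO 3, 17 on the 6 libraries alone and 22 with quality weights. The 6 mitosis rises were 2 without DMSO 1, DMSO 3 or WM-3835 1, 3 without WM-3835 2 or WM-3835 3, 3 with RLE or upper-quartile scaling, 15 on the 6 libraries alone and 16 with quality weights, and the list did not pass by fry (adjusted p = 0.0648).

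Families of housekeeping genes shifted by small amounts. Of 80 ribosomal protein genes, 14 fell, and 15 adjusted over the list alone (median -0.18, camera adjusted p = 1.18e-05; adjusted p = 0.488 with an estimated correlation), with Rps15a at -0.46 (SE 0.08) and Rps19 at -0.50 (SE 0.10). Of 85 genes of oxidative phosphorylation, 16 rose and 1 fell, or 17 and 1 adjusted over the list alone (median 0.14, camera adjusted p = 0.00208; adjusted p = 0.481 with an estimated correlation), with Ndufa13 at 0.52 (SE 0.09) and Atp5g3 at 0.41 (SE 0.07). Of 65 histone genes, 10 fell and 1 rose, the same adjusted over the list alone (median -0.31, camera adjusted p = 0.0168; adjusted p = 0.621 with an estimated correlation), with the linker histones H1f0 (-0.92, SE 0.08) and H1f2 (-1.42, SE 0.16). The signs of these medians were the same with RLE and upper-quartile scaling. The same held for each other list in the knockout or WM-3835 comparison in which it passed by camera. The 14 ribosomal falls were 6 without DMSO 1, 5 without DMSO 2, 6 without DMSO 3, 4 without WM-3835 1 and 5 without WM-3835 2, and 23 with upper-quartile scaling, 30 on the 6 libraries alone and 35 with quality weights. The 16 rises were 10 without DMSO 1, 6 without DMSO 3, 8 without WM-3835 2, 7 without WM-3835 3 and 26 with quality weights. The histone list did not pass without WM-3835 3 (camera adjusted p = 0.095) or by fry (adjusted p = 0.0921).

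Several pathways passed by a narrower margin. Of 20 cholesterol synthesis genes, 7 rose and 1 fell, or 8 and 2 adjusted over the list alone (median 0.11, camera adjusted p = 0.024; adjusted p = 0.484 with an estimated correlation), with Insig1 at 0.80 (SE 0.08). Of 14 genes of the acetyltransferase family of KAT7 and its partners, 5 rose, and 5 adjusted over the list alone (median 0.18, camera adjusted p = 0.0339; adjusted p = 0.266 with an estimated correlation), with the KAT7 partner Jade2 at 0.66 (SE 0.08) and Kat6b at 0.38 (SE 0.09). Of 14 AHR and NRF2 targets, 5 rose and 1 fell, or 6 and 1 adjusted over the list alone (median 0.17, camera adjusted p = 0.0446; adjusted p = 0.266 with an estimated correlation), with the glutathione synthesis gene Gclc at 0.96 (SE 0.10). Of 12 pan-epithelial genes, 3 rose, or 5 rose and 1 fell adjusted over the list alone (median 0.21, camera adjusted p = 0.0446; adjusted p = 0.418 with an estimated correlation), with Elf3 at 1.05 (SE 0.12) and the adhesion gene Epcam at 0.51 (SE 0.06). Of 20 NF-kB genes, 3 fell and 1 rose, or 5 and 1 adjusted over the list alone (median -0.13, camera adjusted p = 0.0446; adjusted p = 0.484 with an estimated correlation), with Birc3 at -0.36 (SE 0.08) and Rela at 0.34 (SE 0.08).

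Each of these 5 lists lost its call with at least 1 library left out. The cholesterol list had a camera adjusted p of 0.0613 without DMSO 1, and its 7 rises were 4 without DMSO 1 or WM-3835 2. The acetyltransferase list had 0.0635 without DMSO 2, and its 5 rises were 3 without DMSO 3 or WM-3835 3. The AHR and NRF2 list had 0.0556 without DMSO 3. The pan-epithelial list had 0.0561 without DMSO 3, and its 3 rises were 6 on the 6 libraries alone or with quality weights. The NF-kB list had 0.0613 without DMSO 1, 0.0775 without WM-3835 1 and 0.0936 without WM-3835 3, and its 3 falls were 5 with RLE or upper-quartile scaling, 7 on the 6 libraries alone and 8 with quality weights. Lists for the other cell types named for the knockout did not pass with WM-3835 (camera adjusted p from 0.0663 to 0.984), nor did that for fibroblasts (5 rose and 3 fell, or 5 and 5 adjusted over the list alone, camera adjusted p = 0.8, upward, with a median of -0.20). By fry, the lists for muscle-like (adjusted p = 0.000643), enterocyte- and hepatocyte-like (0.0291) and red cells (0.0498) passed downward.

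**Figure D2:**
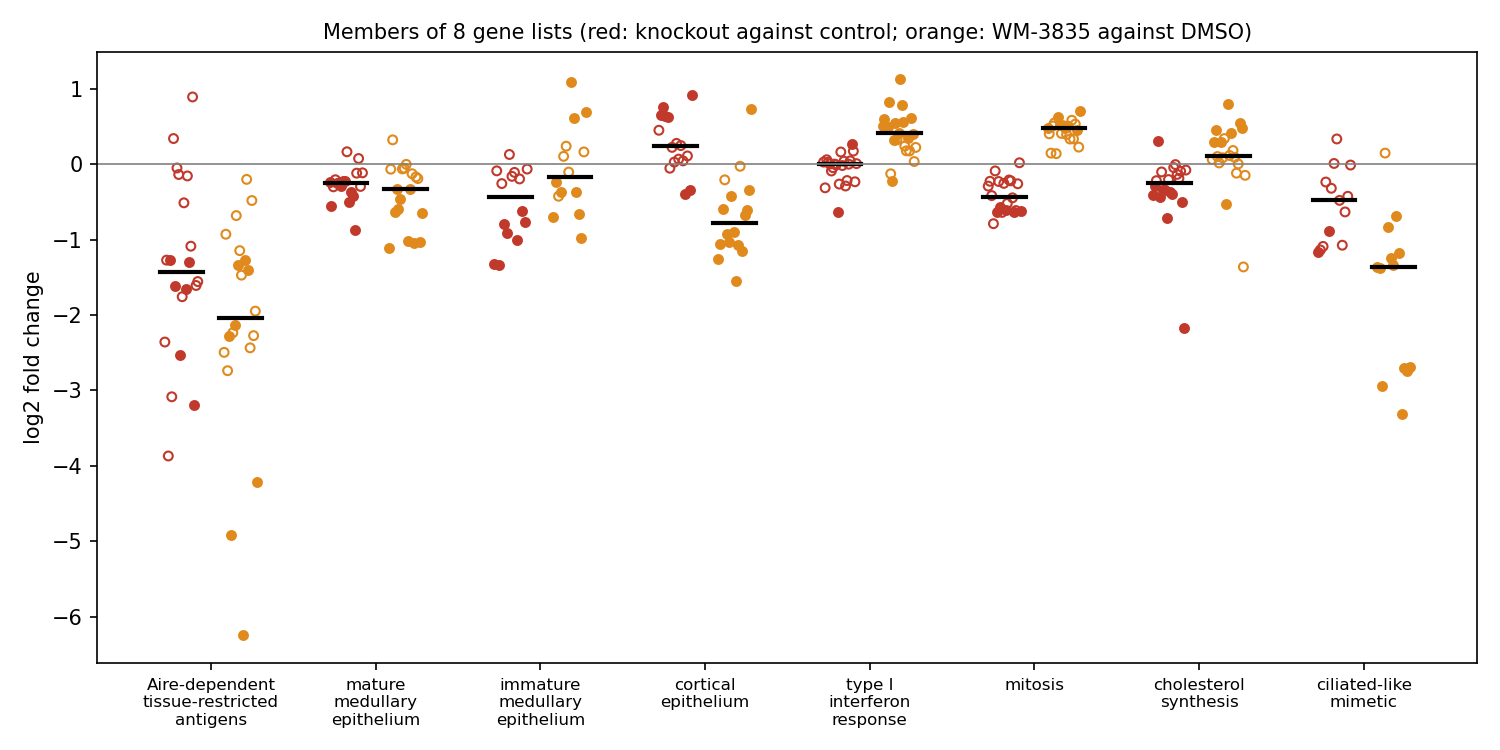
Log2 fold change of each measured member of 8 gene lists, for knockout against control (red) and WM-3835 against DMSO (orange); filled points passed the test at an adjusted p under 0.05, open points did not, and black bars are medians. Antigens that depend on AIRE and mature medullary markers lie mostly below 0 in both, while cortical and mitosis genes lie on opposite sides.

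With WM-3835, 3490 genes were called, 1744 higher and 1746 lower (50% lower, 47% with limma-voom and 60.1% with upper-quartile scaling). More than 2-fold changes were 305 rises and 686 falls. Fitted on its own 6 libraries the comparison called 6070 genes, which held 3472 of the 3490, and with quality weights per group 6589, which held 3470.

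The design also asks whether the inhibitor and the deletion move the same genes. Genes that fell in both numbered 470, against 140.7 for independent lists (3.34 times), and genes that rose in both 287, against 106.7 (2.69 times). Opposite calls were near that level: 153 genes fell in the knockout and rose with WM-3835 (140.5 for independent lists), and 91 did the reverse (106.8). Csn2, Thy1, Ang4, Bpifb5 and H2-DMb2 were in the first group, and Calb1 and Enpep in the second. With Xist as a covariate 246 fell in both (4.22 times) and 123 rose in both (3.29 times), and with knockout 3 alone 196 (4.96 times) and 97 (4.85 times). Other fits gave less. On their own 6 libraries 360 fell in both (2.64 times) and 157 rose in both (2.36 times), and with DESeq2 632 (2.65 times) and 344 (2.31 times). With quality weights per group 369 fell in both (2.69 times) and 191 rose in both (2.73 times). Of the 2646 knockout genes, 68.1% had the same sign with WM-3835, as did 58.3% of the genes not called in the knockout. The comparisons share no control library.

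The genes that fell in the knockout were lower with WM-3835 as a list (median -0.273; camera p = 0.00279 with an estimated correlation), and those that rose were higher (median 0.132; camera p = 0.00809 with an estimated correlation). In the other direction, genes that fell with WM-3835 were lower in the knockout (camera p = 0.00263 with an estimated correlation). Genes that rose with it passed with the preset correlation (camera p = 0.000271) and not with an estimated one (p = 0.107). Among 10000 random lists matched for expression, none had a median with WM-3835 as extreme as those of the knockout genes. Such lists draw genes independently, while the knockout genes vary together (estimated correlation 0.0193 for those that fell and 0.0247 for those that rose). The random lists therefore overstate the certainty. Across genes without Kat7, which are not independent replicates, the log2 changes had Pearson's r = 0.281 and Spearman's rho = 0.268. The former was 0.186 without control 1 and 0.149 without the filter on low counts. The effects differed for 1887 genes, 824 with the higher change in the knockout and 1063 with the lower, and for 1176 (1108 shared) with Xist as a covariate. The share with the lower change in the knockout, 56.3%, depended on the fit: it was 49.7% with upper-quartile scaling, 50.1% without control 1 and 58.3% with Xist as a covariate. Each effect has its own reference group, and the control and DMSO cultures also differed from each other.

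**Figure D3:**
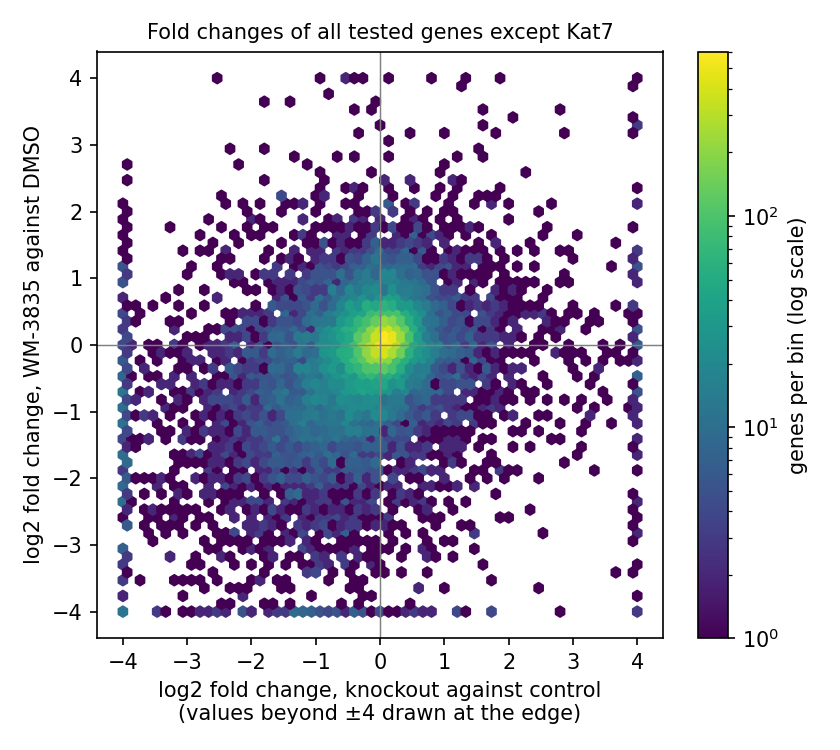
Log2 fold change of each tested gene except Kat7 in the knockout (horizontal) and with WM-3835 (vertical), as a count of genes per bin on a log colour scale; values beyond 4 are drawn at the edge. Most genes lie near 0, and the quadrant in which both changes are negative is the fullest away from the centre.

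Direction was compared with expression level because AIRE is known to act on genes of low expression, and in both comparisons most calls among such genes were falls. In the lowest quartile of mean expression, 86.9% of the knockout calls and 89.9% of the WM-3835 calls were lower. Few genes of that quartile were called, 229 of 4668 in the knockout and 169 with WM-3835. In the highest quartile the shares were 37.1% and 42.9%. Over all genes of the lowest quartile, called or not, the median log2 change was -0.464 in the knockout and -0.438 with WM-3835.

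**Figure D4:**
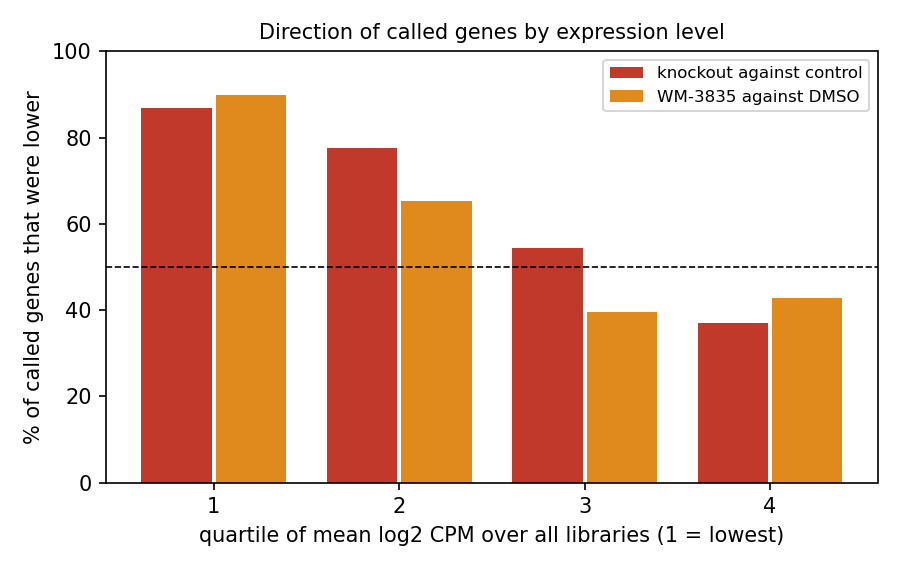
Share of called genes that were lower, in percent, by quartile of mean log2 CPM over all libraries (1 is the lowest), for knockout against control (red) and WM-3835 against DMSO (orange); the dashed line marks an equal split. The share falls from 86.9% to 37.1% in the knockout and from 89.9% to 42.9% with WM-3835.

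Fewer genes were detected with WM-3835 at equal depth, by more than the spread between libraries but at the limit of the test. Genes with at least 1 count numbered 19176 ± 413 with WM-3835 and 20162 ± 457 with DMSO (SD, n = 3 each; difference -986, exact permutation p = 0.1, the smallest possible). In the knockout they numbered 18517 ± 143 against 18805 ± 884 in control (difference -288, exact permutation p = 0.7), within the spread of the controls. Without control 1 the knockout difference was 176, and without control 3 it was -708. For genes with at least 10 counts the difference was -453 in the knockout and -680 with WM-3835 (exact permutation p = 0.1 each).

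The control and DMSO cultures, which differ in treatment and genotype label, also differed from each other. Tuft-cell genes were lower in DMSO for 15 of 15 measured, and for 15 adjusted over the list alone (median -3.36, camera adjusted p = 2.94e-24; adjusted p = 0.0674 with an estimated correlation), with Avil at -3.45 (SE 0.15), the ion channel gene Trpm5 at -3.62 (SE 0.17) and Dclk1 at -2.87 (SE 0.16). Of 17 keratinocyte genes, 12 were lower, and 14 adjusted over the list alone (median -1.29, camera adjusted p = 2.98e-06; adjusted p = 0.0414 with an estimated correlation), with the skin barrier genes Flg (-2.28, SE 0.34) and Spink5 (-1.40, SE 0.19). Immature medullary markers were lower for 10 of 14 and higher for 1, or 11 and 1 adjusted over the list alone (median -0.66, camera adjusted p = 1.2e-06; adjusted p = 0.0911 with an estimated correlation), with Cldn3 at -1.82 (SE 0.14) and Ly6a at -1.49 (SE 0.12). Stress response genes were higher in DMSO for 13 of 16, or 15 higher and 1 lower adjusted over the list alone (median 0.89, camera adjusted p = 9.05e-11; adjusted p = 0.177 with an estimated correlation), with Trib3 at 1.76 (SE 0.20) and Sesn2 at 1.19 (SE 0.09). Ribosomal protein genes were higher for 46 of 80, and 58 adjusted over the list alone (median 0.36, camera adjusted p = 7.93e-15; adjusted p = 0.177 with an estimated correlation), with Rpl12 at 1.05 (SE 0.13). Aire was higher in DMSO by 0.92 (SE 0.08, adjusted p = 8.75e-08). The antigens that depend on AIRE were not higher there. Of 20 measured, 1 was lower, and none adjusted over the list alone (median -0.58, camera adjusted p = 0.4, downward). Fibroblast markers were lower in DMSO for 7 of 15 and higher for 1, the same adjusted over the list alone (median -1.23, camera adjusted p = 0.00622; adjusted p = 0.177 with an estimated correlation). Type I interferon genes were also lower for 14 of 22 (median -0.35, camera adjusted p = 3.06e-06). Immediate early genes were lower for 10 of 15 and higher for 3 (median -0.61, 9.03e-05). Pan-epithelial genes were lower for 7 of 12 and higher for 1 (median -0.51, 0.000484). Enterocyte- and hepatocyte-like (median -0.75, 0.0172) and cornified envelope genes (median -0.71, 0.0306) were lower for 4 of 16 each. With an estimated correlation the adjusted p of these lists was 0.177 or 0.406. In all 16 of 49 lists passed, 13 lower and 3 higher in DMSO. The tuft, immature medullary, fibroblast, immediate early, enterocyte- and hepatocyte-like and cornified envelope lists were lower both in the knockout and in DMSO. For these lists, a fall in the knockout cannot be told from a high level in the controls. In total 4600 genes differed, 2121 higher and 2479 lower in DMSO (53.9% lower, 48% without control 1 and 61.4% on the 6 libraries alone).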

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

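The 3 patterns weighed here were picked after the results had been seen, while the outcome that would speak for or against each explanation was written down before its test was run; the fits with Xist as a covariate and with quality weights per group, and the look at single transcripts abundant in adipocytes, were added after seeing the data.

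The effects of the knockout and of WM-3835 differed, by edgeR's test of the difference itself, for 1887 genes and for 62 of the 111 genes named in the main comparisons. By camera with the preset correlation, they differed for 13 gene lists. Random splits of the libraries gave fewer: 100 of the 200 splits within the comparisons were drawn, 1 gave as many genes (the real one), and the highest other gave 1302. That split kept WM-3835 and DMSO as labelled, splits with these 2 labels exchanged gave up to 1189, and among drawn splits that mixed WM-3835 and DMSO libraries the highest gave 90. Such splits ask whether a treatment has an effect, not whether the effects are equal, so they cannot decide the latter. Splits that mix groups also put treatment effects into the spread between libraries, so few calls in them were fixed in advance. For the single comparisons 10 splits exist, too few for a share under 0.05: 1 of 10 gave as many genes, the real one, with 2646 calls in the knockout, 3490 with WM-3835 and 4600 for DMSO against control, and the highest other split gave 0 by edgeR in each. At an unadjusted p under 0.05 the real splits gave 5169, 5571 and 6520 genes, and the highest others 1889, 288 and 1252.

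Each value that follows is the knockout change minus the WM-3835 change on the log2 scale, with an adjusted p of at most 0.0483 for the genes. Each change has its own reference group, and DMSO and control differed from each other for 4600 genes. These values therefore cannot tell unlike effects from unlike references. Aire, for example, was higher in DMSO than in control by 0.92, and Ndrg1 stood at 590 CPM in control and 280 CPM with DMSO. Among the genes named first for the knockout, the difference was -6.93 for Kat7, 8.48 for Xist, 2.32 for Gpr85, 2.09 for Catsperg1, 1.71 for Scn1a and 1.67 for Lonrf2. It was -2.37 for Mmp13, -2.46 for Muc2, -2.66 for Cpe and -3.42 for Hbegf. Among those named first for WM-3835, it was -5.69 for Angptl4, -4.59 for Pdgfra, -4.38 for Pdk4, -3.87 for Plekhd1, -2.74 for Ifi207, -2.62 for Acot1, -1.40 for Tac1 and -1.34 for Elapor1. It was 2.45 for Slc1a2, 2.35 for Neu2, 2.31 for Slc6a15 and 1.87 for Tmem132e.

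Aire differed by 0.87 and the antigen gene Csn2 by 1.00, and among cortical and medullary genes Cd83 differed by 1.83, Ly75 by 1.35, Il7 by 1.20, Ctsl by 0.92, Cd40 by 0.43, Trp63 by 0.36 and Tnfrsf11b by -0.64. The cilia regulator Mcidas differed by 2.68. Among cell cycle and replication genes, Mcm6 differed by -0.92, Plk1 by -1.08, Bub1b by -1.09, Hmmr by -1.32 and Tpx2 by -0.71. Among interferon genes, Irf7 differed by -0.82 and Oasl1 by -0.96. Among stress and signalling genes, Sesn2 differed by 0.76, Dnajb9 by 0.53, Rela by -0.47, Xbp1 by -0.75, Ier3 by -0.85 and Dusp1 by -1.64. In lipid and redox metabolism, Lpl differed by 1.68, Hmgcs1 by -0.47, G6pdx by -0.62, Gclc by -0.91, Acot2 by -0.94, Insig1 by -1, Acaa2 by -1.01, Acadl by -1.09 and Plin2 by -2.13. Among epithelial and matrix genes, Epcam differed by -0.48, Elf3 by -1.29 and Tgfbi by -1.46. Atp5g3 of the respiratory chain differed by -0.34, and the hypoxia genes Ldha, Slc2a1, Car9 and Ndrg1 by -1.25, -1.86, -2.21 and -2.23.

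Among lists, the median difference was 0.95 for cortical epithelium (camera adjusted p = 2.19e-12), 1.02 for ciliated cells (0.00135) and 0.55 for the stress response (0.000106). It was 0.12 for ribosomal proteins (0.0164). It was -0.45 for the interferon response (1.03e-08), -0.81 for mitosis (1.08e-08), -0.42 for DNA replication (0.000443) and -0.46 for cholesterol synthesis (7.49e-07). It was -0.68 for immature medullary epithelium (0.00541), -0.52 for microfold cells (0.00541), -0.79 for the cornified envelope (0.0218), -0.70 for fibroblasts (0.0324) and -0.21 for immediate early genes (0.0158). With an estimated correlation the adjusted p of these 13 lists ranged from 0.345 to 0.73, so their camera calls rest on the preset correlation. By fry, the lists of the stress response (adjusted p = 0.118), ribosomal proteins (0.328) and immediate early genes (0.19) did not pass. The others passed by fry, at adjusted p from 0.00318 to 0.0392.

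Most calls among genes of low expression were falls in both comparisons, though 4.9% of the lowest quartile was called in the knockout and 3.6% with WM-3835. A difference in depth is argued against by thinning: with every library at 26473241 counts, 87.7% of called genes of the lowest quartile were lower in the knockout and 90.7% with WM-3835. Random dropout of rare transcripts leaves the summed CPM of a fixed set of genes unbiased. That sum fell to 0.706 of control in the knockout and to 0.774 of DMSO with WM-3835. Each treated library lay below each reference library (exact permutation p = 0.1, the smallest possible). The quartile was drawn on mean log2 CPM of the same libraries, which can raise the sum of a group with uneven counts. The coefficient of variation was 0.469 in control and 0.294 in the knockout, so the knockout ratio cannot decide on dropout. It was 0.103 with DMSO and 0.125 with WM-3835. The mean sum was 4822.2 CPM in control, 3404.4 in the knockout and 3358.4 with DMSO. The wild-type DMSO cultures thus lay near the knockout. The knockout ratio cannot tell a fall in the knockout from a high level in the controls. The share of counts from mitochondrial genes was higher in each treated library than in each reference library (3.84% to 4.22% against 3.16% to 3.48% in the knockout, 3.04% to 3.61% against 2.69% to 2.78% with WM-3835), so a difference in cell or RNA quality stays open and was not tested. A change in the mix of TEC subtypes, each with its own rare transcripts, may contribute and was not tested.

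The knockout calls come from a group in which 2 of 3 libraries held Xist, set against controls without it. Sex as the whole cause is argued against by the third library: genes called from the others kept their direction in knockout 3 in 85.4% of cases, the mean over 3 left-out controls, against 57.7% to 61.1% of genes not called. Also, 68.1% of the knockout genes had the same sign with WM-3835, where all 6 libraries held Xist, against 58.3% of genes not called. Calls fell from 2646 to 1057 with Xist as a covariate. Xist nearly follows the groups, so a loss of precision may contribute to that drop, which was not tested. List medians moved both ways (immature medullary -0.46 against -0.44, mature medullary -0.16 against -0.25, tuft -0.65 against -0.42, mitosis -0.37 against -0.43, stress response 0.13 against 0.23), and Aire went from -0.24 to -0.17. In the main fit, 15.2% of genes on X were called against 14.2% on autosomes. Sex may account for some calls, which these values do not exclude, and the wider spread among the controls stays open as well, since quality weights per group left 1180 calls.

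Targets of PPAR, receptors that turn on fat oxidation, rose with WM-3835 as a list that left out the genes already seen (camera adjusted p = 1.24e-06; adjusted p = 0.0377 with an estimated correlation). Adipocytes among the sorted cells are argued against: the median log2 change of 9 adipocyte markers was -0.49 (camera adjusted p = 0.853, upward), and transcripts abundant in adipocytes stayed low, Adipoq at 0.633 CPM with DMSO and 0.362 CPM with the inhibitor and Fabp4 at 16.5 and 10.7 CPM, while the target Acadl gained 61.2 CPM. Of the 9 only Pnpla2, at 101 CPM with DMSO, rose (0.76, SE 0.10, adjusted p = 1.66e-05), 7 had a mean log2 CPM below 1, and fibroblast markers moved both ways (5 rose and 3 fell). An effect of the compound that does not pass through KAT7 could account for the rise, as the same list did not pass in the knockout (camera adjusted p = 0.184) and differed between the effects (camera adjusted p = 0.000169; adjusted p = 0.0607 with an estimated correlation). No sample with another inhibitor or with WM-3835 on knockout cultures exists here to test it.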

How the results depend on the processing

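Quality weights per group, robust edgeR, Xist as a covariate, knockout 3 alone and the fit without X and Y genes were chosen after seeing the data; the other alternatives were planned. Of the main results' values under alternatives, 191 stayed: tests kept direction and side of the threshold, counts lay within 1.5 times, and differences in genes detected lay within 1 SD between libraries, where the knockout difference changed sign without control 1 (176). Of the rest, 9 lost the call, 2 gained it and 9 counts moved by over 1.5 times. Of 2259 values of named genes, 2160 kept direction and call, 87 lost the call and 12, all of Fabp4 with WM-3835, gained it, and no sign reversed; of 756 counts of list members, 610 stayed within 1.5 times.

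Fitted on their own 6 libraries, the knockout comparison called 1157 genes and WM-3835 against DMSO 6070. Quality weights gave 1180 and 6589. The opposite moves follow from the spread, which is wide among controls and narrow with DMSO and WM-3835, while the fit to 12 libraries shares 1 estimate. Xist as a covariate gave 1057 knockout calls and 1176 genes whose change differs, and knockout 3 alone gave 704, with fewer samples; the test of sex itself is given among the patterns weighed above. With an estimated correlation, camera passed 0 lists in the knockout and 0 with WM-3835, against 13 and 17 with the preset one; fry passed 17 and 23, ended calls named in the report, and turned the acetyltransferase list, which holds Kat7, downward in the knockout (0.00059); at an unadjusted p under 0.05 the estimated correlation left 5 and 9. The cause was not tested.

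The fall of Aire in the knockout was -0.2357 without a filter on low counts (adjusted p = 0.0508), -0.2473 on the 6 libraries (0.0904), -0.2407 with quality weights (0.152), -0.169 with Xist as a covariate (0.333) and -0.1223 with knockout 3 alone (0.57). The rise of Kat7 with WM-3835 was 0.1822 on the 6 libraries (adjusted p = 0.026) and 0.1835 with quality weights (0.0114). The cause was not tested beyond the smaller sample and the spread.

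Leaving out each replicate in turn gave 1773 to 2792 knockout calls, 2393 to 2689 with WM-3835, 1346 to 2232 for the difference and 3257 to 4778 for DMSO against control. Kat7 ranged from -6.838 to -6.565 in the knockout and 0.1637 to 0.1953 with WM-3835. Aire ranged from -0.2862 to -0.1684 in the knockout, losing its call without control 2 (-0.1872), control 3 (-0.2272), knockout 1 (-0.2362) or knockout 2 (-0.1684). It ranged from -1.155 to -1.05 with WM-3835 and from 0.8933 to 0.9783 for DMSO against control. Passing lists numbered 9 to 15 and 15 to 18, knockout genes with the same sign under WM-3835 64.5% to 70.6%. Differences in genes detected ranged from -708 (without control 3) to 176 (without control 1) for the knockout and from -1234 to -754 for WM-3835. DESeq2 called 3399, 4075, 2499 and 5109 genes in the 4 comparisons.

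With the replicate number as a block, 2393, 3360 and 1884 genes were called for the knockout, WM-3835 and the difference. Same-numbered libraries showed no clear pairing: their deviations from group means correlated at 0.002 to 0.009 in the knockout comparison and 0.003 to 0.058 with WM-3835. Pairs of unlike number gave -0.009 to 0.004 and -0.056 to 0.017. Not every library correlated best with its own number, but weak pairing stays open. The block ended the calls of the pan-epithelial list with WM-3835 (adjusted p = 0.0628) and of Ptgs1, a tuft-cell gene, in the knockout (0.0683). It brought in the stress response list, downward (0.026), and the fall of Fabp4 (0.0113) with WM-3835. It changed no other call among the named genes and the lists of these comparisons. The stress response list with WM-3835 had a camera adjusted p of 0.0523 in the main fit (5 of 16 fell and 2 rose). It also passed by camera with RLE scaling (0.0457) and without DMSO 2 (0.00739), WM-3835 1 (0.0384) or WM-3835 3 (0.00817), and not by fry (adjusted p = 0.251). The share of the lowest quartile that was called was 5.8% after thinning to equal depth and 4.9% before in the knockout, and 5% and 3.6% with WM-3835. Quartiles were drawn anew over fewer genes, and the upper edge of the lowest moved from 0.81 to 1.18 log2 CPM. It thus held other genes, so these shares cannot show whether depth set a limit.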

Other observations

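The lists in this part and their tests were chosen after the gene results had been seen, and the stricter count of neighbours and that of risen genes were added after the first count was known.

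Genes of glycolysis and the response to low oxygen fell together in the knockout. Of 23 measured genes that had not been looked at before, 20 fell, and 21 adjusted over the list alone (median log2 change -0.71, camera adjusted p = 3.93e-22; adjusted p = 0.0274 with an estimated correlation). Ndrg1, a marker of hypoxia, fell by 2.07 (SE 0.18), Car9, an acid-base enzyme induced by low oxygen, fell by 2.06 (SE 0.42), the glucose transporter gene Slc2a1 fell by 1.40 (SE 0.22) and the lactate dehydrogenase gene Ldha fell by 0.97 (SE 0.10). The mean log2 CPM of the list was 7.67, 7.31 and 7.21 in the controls and 6.56, 6.62 and 6.59 in the knockout libraries. The DMSO libraries, at 6.94, 6.92 and 6.96, lay below the controls too. With WM-3835, 4 of the 23 rose and 2 fell, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.0243; adjusted p = 0.639 with an estimated correlation). The fall may reflect lower oxygen in the control cultures as well as loss of KAT7. The count of 20 was 18 to 20 without single replicates, 16 with Xist as a covariate and 13 with knockout 3 alone, and the cause was not tested.

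Part of the measured genes that handle fatty acids rose with WM-3835. Of 30 measured PPAR targets and fatty acid oxidation genes, 14 rose and 1 fell, or 15 and 1 adjusted over the list alone (median 0.38, camera adjusted p = 1.24e-06; adjusted p = 0.0377 with an estimated correlation). Acot2, a mitochondrial acyl-CoA thioesterase, rose by 1.17 (SE 0.12), Plin2, which coats lipid droplets, by 1.10 (SE 0.23), and the oxidation enzymes Acaa2 and Acadl by 1.08 (SE 0.13) and 1.02 (SE 0.08). The exception was Lpl, the lipoprotein lipase, which fell by 1.07 (SE 0.12). In the knockout 5 rose and 1 fell, the same adjusted over the list alone (median 0.03, camera adjusted p = 0.184). Plin2 was the one that fell by 1.03 there (SE 0.23), and Lpl rose by 0.60 (SE 0.12).

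Genes that fell lay next to each other more often than permuted calls do. In the knockout 23.9% of fallen genes had a fallen neighbour on the chromosome, against a mean of 15.6% when calls were permuted within expression quartiles (permutation p = 0.001, the smallest that 1000 permutations can give). With WM-3835 the share was 26.1% against 18.2% (permutation p = 0.001, again the smallest possible). Tandem gene families and overlapping reads could give such pairs. Counting only neighbours more than 10 kb apart whose symbols differ in the first 3 letters, the shares were 12.7% against 7.3% in the knockout and 12.3% against 8.6% with WM-3835 (permutation p = 0.001 each). Genes that rose lay together too, with shares under the stricter count of 7.5% against 5.6% in the knockout (permutation p = 0.02) and 11.8% against 8.4% with WM-3835 (permutation p = 0.001), so the grouping is not confined to falls, and its cause was not tested.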
